A study of Brassica napus with 12 samples.

How the data were processed

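The samples were immature seeds of 4 inbred lines of Brassica napus (rapeseed) named A28, R8Q10, SW and YH25005, collected 24 days after pollination, with 3 libraries per line. The labels name the tissue as seeds and the extraction protocol speaks of embryos, so which of these entered the RNA preparation is not settled by the labels. Nothing in the labels says whether the replicates came from separate plants or plots, so p-values measure only the spread between these samples, which may be technical. The series is about lines with high or low linolenic acid in the seed oil, and the labels do not say which line has which trait, so no line is called high or low here.

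Per the labels' protocols, poly-A RNA was made into libraries with a kit whose protocol does not mention strand, and read pairs were sequenced on an Illumina instrument. Reads from overlapping or antisense genes therefore cannot be told apart. The submitters' processing notes name bcl2fastq, HISAT2 and DESeq2 without versions. The genome build, the annotation and the counting program are not given in the sources used here. Rapeseed is an allotetraploid with an A and a C subgenome, so most genes have a near-identical homoeologous copy. How the authors' counting treated reads that match both copies is not given in the sources used here, and levels of single copies carry that uncertainty.

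Each deposited file holds, per the file headers, a read count and an FPKM value per gene for 1 library. The counts deposited by the authors were whole numbers and were analysed as counts. The FPKM values deposited by the authors served only to compare gene lengths between gene lists and entered no test. Every file was assigned to its line from the sample title.

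The gene rows were not the same in all files. The 6 libraries of A28 and R8Q10 shared a list of 47207 genes, and the 6 libraries of SW and YH25005 shared a list of 46839. In total 50338 genes were listed, 43708 of them in both lists, 3499 only in the first and 3131 only in the second. Every listed gene exceeded 1 CPM in at least 3 of the 6 libraries of its list, so a gene missing from a list had been filtered and is not a measured 0. Tests across lines used the 43708 genes in both lists. Library size was the total over all listed genes. Genes the authors added to the annotation are numbered, and the numbering was checked between lists from the ratio of count to FPKM. The check covered only genes with at least 100 counts in each of the 12 libraries. Of 531 such added genes 97.0% had lengths within 10% of each other, against 94.7% of 22661 annotated genes. Added genes with fewer counts in any library were not checked.

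Of the gene IDs, 20131 of the shared genes carried an A subgenome ID, 21394 a C subgenome ID, 2093 were genes added by the authors and 90 had no subgenome. IDs of 37457 shared genes name a chromosome. The reference table available here, of the Da-Ae assembly, matched 2185 IDs and gave a name for 2, so genes are reported by ID and no coordinates are printed. Of 1968 matched IDs on chromosomes, 92.5% lay on the chromosome that the ID names, and the rank correlation between ID order and reference order was 0.88 in the median chromosome and 0.64 in the lowest. The 17 gene lists fixed before the data were examined (fatty acid synthesis, desaturases, elongation, triacylglycerol assembly, oil body proteins, storage proteins, maturation regulators, late embryogenesis proteins, fatty acid breakdown, photosynthesis, seed coat flavonoids, seed coat mucilage, endosperm, glucosinolates, cell division, heat shock and ribosomal proteins) had 0 members that could be matched to an ID. No gene list test was therefore run.

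Total counts ranged from 30150457 to 40762254 per library. The limit that a count of 0 allows, 3 counts, corresponded to 0.0736 CPM in the deepest library and 0.0995 CPM in the shallowest. Floors cover counting error only. A fold against a line with 0 counts in all 3 libraries was computed against 3 counts over the line's 3 libraries. Folds used library totals without the TMM factors of the tests, while the CPM printed beside them are scaled with these factors. Each fold is therefore a lower bound for unscaled CPM only. Where YH25005 is the lower line, with TMM factors of 0.7795, 0.9141 and 0.7662, the bound for scaled CPM is lower.

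Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit and F test, TMM scaling, 1 coefficient per line, all 12 libraries in 1 fit, filterByExpr), with Benjamini-Hochberg adjustment and a threshold of 0.05. The filter removed 0 of the shared genes. A gene was said to separate a pair of lines from the other pair when all 4 contrasts between the pairs passed with the same sign. All 6 line pairs and all 3 pairings were treated alike. Measures of whole libraries were compared with an exact permutation test over the 15400 partitions of 12 libraries into 4 groups of 3, with 4 measures in the family.

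The tests were tested on simulated data drawn from the real means and library sizes, with 200 genes changed. Apart from these changes, each gene had the same mean and the same dispersion in all lines. The real lines differed in spread, with a biological coefficient of variation of 0.5 in A28 and 0.26 in YH25005. The false calls given here therefore say nothing about error under unequal spread. For A28 minus YH25005 the fit recovered 0 of 50 genes changed 1.5-fold, 1 of 50 changed 2-fold, 22 of 50 changed 4-fold and 34 of 50 changed 8-fold, among 43708 genes, with 2 false calls of 59. For the pairing of A28 and SW against R8Q10 and YH25005 it recovered 17 of 50 at 4-fold and 32 of 50 at 8-fold. The first acceptance bound of this test, recovery of most 4-fold genes, was not met and was replaced by a bound on 8-fold genes, so the recovery is low when few genes change.

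The rule for the IDs named was fixed before the data were examined: with no gene names, at most 2 IDs higher and 2 lower per comparison, with the largest fold change among called genes whose libraries do not overlap and whose higher line has at least 10 CPM. For pairings, the smallest of the 4 fold changes was ranked.

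Runs of neighbouring genes were sought after the data had been examined, following 2 earlier exploratory scans with other settings. Genes were ordered by the number in their ID along 19 chromosomes, and each gene's log2 CPM (pseudocount 0.1) in a line was set against the median of the other lines, for genes of at least 1 CPM in that median. Genes at or below -2 scored towards a low run and genes at or above 0.5 towards a raised run, each other gene costing 0.5 or 1. A run was kept when its score exceeded the highest score in 200 shuffled orders. The scan recovered 1 of 1 planted run of 40 genes in simulated data. The list of homoeologous chromosomes (A10 with C9, A3 with C3 and so on) was also written after the runs were seen.

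Replicate numbers are shared between lines, and whether same-numbered libraries deviate together from their line means was checked across genes. For A28 and R8Q10 the 3 correlations were 0.12, 0.58 and 0.43, all above 0.1, so the numbers were taken to pair these lines, from the data and not from the labels. The limit of 0.1 was not set against correlations that arise by coincidence, so this pairing is an assumption. In each of the other 5 pairs of lines at least 1 of the 3 was below 0.1.

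Alternatives fixed before the data were examined were RLE and upper-quartile scaling, scaling without the 50 most abundant genes, DESeq2 1.42.0, no filter, a stricter filter, the replicate number as a block, each library left out, a fold change minimum and a fit of only the lines compared. Alternatives added after the data had been examined were a covariate for the main component within lines, all genes of the shared list, counts without genes inside runs, a replicate block with only A28 and R8Q10 in the fit, and other run settings.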

Results

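Seed transcriptomes of 4 rapeseed inbred lines, A28, R8Q10, SW and YH25005, were compared 24 days after pollination, with 3 libraries per line. The study asked how lines with high and low linolenic acid, a polyunsaturated fatty acid of seed oil, differ at this stage. Library totals lay between 30150457 and 40762254 counts. Correlations of log2 CPM across genes between replicates ran from 0.798 (A28 replicates 2 and 3) to 0.952. The biological coefficient of variation was 0.5 in A28, 0.34 in R8Q10, 0.35 in SW and 0.26 in YH25005. Principal components were taken from the 43708 genes in both lists, so genes filtered from either list could not contribute. The first component, with 34.5% of the variance, placed A28 and SW on one side and R8Q10 and YH25005 on the other. The second component (26.7%) parted R8Q10 from YH25005 and the third (20.9%) parted A28 from SW.

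**Figure D1:**
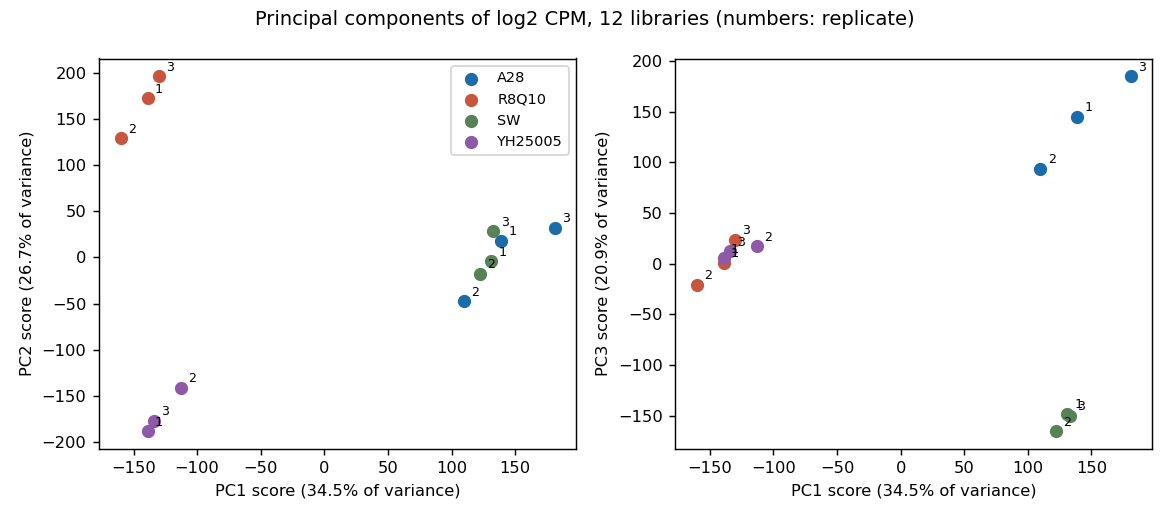
Scores of the 12 libraries on the first 3 principal components of log2 CPM, taken from the genes in both lists. The percent of variance is on each axis and the replicate number beside each point. On the first component the A28 and SW libraries lie between 110 and 181 and the R8Q10 and YH25005 libraries between -160 and -113.

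A few abundant genes took a far larger part of the RNA in YH25005 than in the other lines. Its 50 most abundant genes held 22.52% ± 4.25 of the counts (SD, n = 3), against 6.19% ± 1.25 in A28, 7.98% ± 1.28 in R8Q10 and 8.21% ± 1.26 in SW, each library with its own top 50. The lines differed in this share (exact permutation test over 15400 partitions, one-sided on the spread between lines, n = 3 per line, p = 0.00377, adjusted 0.00503). Among the genes in both lists, the 50 most abundant in YH25005 took 16.9% to 23.8% of its counts and 1.58% to 6.22% in the other 9 libraries. Genes on the SW and YH25005 list only could not enter this set, unlike the top 50 of each library above. Of these 50 genes, 33 were lower in A28, 25 in R8Q10 and 27 in SW, and 1 was higher in SW (edgeR quasi-likelihood test, adjusted p below the threshold). Their median log2 fold change against YH25005 was -5.18 in A28, -3.29 in R8Q10 and -3.05 in SW. Genes chosen for their level in a line tend to be lower elsewhere, so the top 50 of each other line was taken the same way. The SW set had 32 genes lower in A28, 40 in R8Q10 and 40 in YH25005, at medians of -1.82, -2.22 and -1.79. The A28 and R8Q10 sets had medians between -0.85 and -0.2 and at most 13 lower genes.

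**Figure D2:**
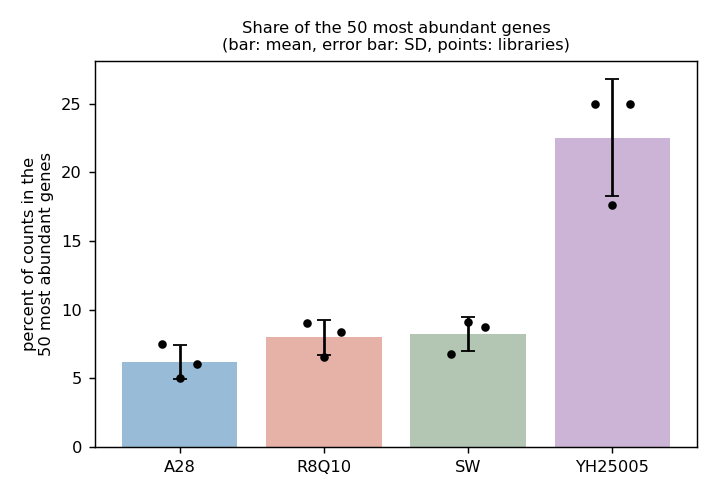
Percent of counts in the 50 most abundant genes of each library, with points for libraries, bars for line means and error bars for the SD (n = 3). The 3 YH25005 libraries lie between 17.61% and 25%, and the highest other library, SW replicate 2, is at 9.132%.

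The A subgenome supplied a smaller part of the transcripts in R8Q10 than in the other lines. Among counts assigned to either subgenome its A share was 46.59% ± 0.46 (SD, n = 3), against 48.88% ± 0.46 in A28, 49.81% ± 0.12 in SW and 49.47% ± 0.18 in YH25005. The exact permutation p over the partitions was 6.49e-05, the smallest they can give, with an adjusted value of 0.00026. Without the genes inside the low and raised runs described next, the shares were 47.93% ± 0.49 in R8Q10, 48.07% ± 0.46 in A28, 48.39% ± 0.11 in SW and 48.87% ± 0.16 in YH25005.

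Stretches of neighbouring genes were low in 1 line, or in some cases 2, relative to the other lines. In R8Q10, 643 genes of chromosome A10, from BnaA10g12730D to BnaA10g25160D, had a median log2 difference of -5.72 from the other lines (quartiles -6.99 and -4.22). Of these genes, 366 had at most 3 counts in the 3 R8Q10 libraries together. In the same line 699 genes of C9, the homoeologous chromosome, from BnaC09g35230D to BnaC09g50090D, were raised by a median of 0.84 (quartiles 0.49 and 1.16).

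In SW, 243 genes at the start of C3, from BnaC03g00020D to BnaC03g05740D, were low with a median of -4.07, and 212 genes at the start of A3 were raised by 0.93. In A28, 92 genes of C8 were low at -5.59 while 79 genes of A9 were raised by 0.97, and 87 genes of C2 were low at -3.79 while 66 genes of A2 were raised by 1.04. In YH25005, 66 genes of A9 were low at -6.46 and 56 genes of C9 were raised by 1.02. The start of C9 was low in both A28 (94 genes, -2.62) and YH25005 (79 genes, -3.85), each with a raised run at the start of A9. In all, 26 low and 17 raised runs were found, covering 3408 genes. Each run scored above the highest of 200 shuffled gene orders, which was the rule for keeping a run and so gives no separate support. The scan was devised after the data had been examined, and gene order was taken from the IDs.

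**Figure D3:**
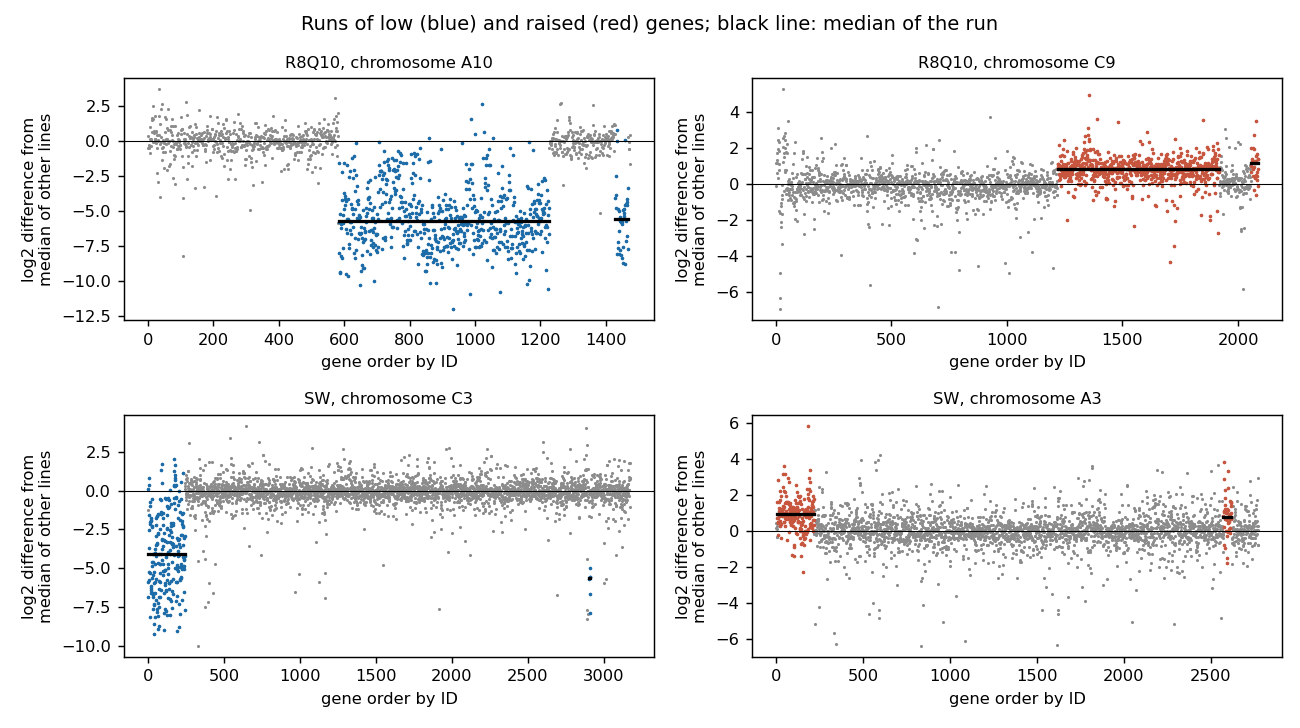
Log2 difference of each gene from the median of the other lines along chromosomes A10 and C9 in R8Q10 and C3 and A3 in SW, in ID order, with low runs in blue, raised runs in red and run medians as black lines. In R8Q10 the long A10 run lies at a median of -5.72 and the long C9 run at 0.84.

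Across the 4 lines 20209 of 43708 genes (46.2%) differed (edgeR quasi-likelihood F test, Benjamini-Hochberg adjusted p at the 0.05 threshold). Each of the 6 pairs of lines is given next in the same way, since the labels do not say which lines share the oil trait. The IDs named had 0 counts in all libraries of the lower line, so folds are lower bounds, taken on library totals without TMM factors. The CPM beside them are TMM-scaled. Bounds for scaled CPM are lower where YH25005 is the lower line, and for A28 or R8Q10 above SW.

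A28 and R8Q10 differed most on chromosome A10, where 750 of 1489 genes were higher and 78 lower in A28. On C9 the reverse held, with 142 of 2151 genes higher and 445 lower. BnaA01g06440D stood at 573 ± 56.5 CPM (SD, n = 3) in A28 and was at least 22100-fold lower in R8Q10, and BnaA10g19670D, inside the low A10 run, was at 420 ± 154 CPM and at least 16400-fold lower. BnaCnng01440D was at 285 ± 85.5 CPM in R8Q10, at least 10400-fold above A28. BnaC08g45610D, inside the C8 run that was low in A28, was at 99.1 ± 3.35 CPM in R8Q10, at least 3650-fold above A28. In total 5256 genes were higher and 4207 lower in A28, 9463 together, and 7800 of them by at least 2-fold (edgeR, adjusted p at 0.05). With only these lines in the fit, 6209 were called, and 9133 when the replicate number was added to that fit as a block, with 4521 higher and 4612 lower in A28, so the excess of higher genes did not hold there.

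A28 and SW gave the lowest count of the 6 pairs in the fit of all libraries, though not without R8Q10 replicate 3, where R8Q10 and YH25005 gave 6404 and A28 and SW 6539. Genes lower in A28 were frequent on A3 (347 of 2825, against 173 higher) and genes higher in A28 on C3 (380 of 3214, against 171 lower). BnaAnng40150D was at 152 ± 51.7 CPM in A28 and, before TMM scaling, at least 5580-fold lower in SW. Brassica_napus_newGene_17810, a gene added by the authors, was at 195 ± 99.6 CPM and BnaCnng01440D at 222 ± 66.1 CPM in SW. They were at least 6800-fold and 7700-fold above A28. The added gene had too few counts in A28 for the check of numbering between lists. The test called 3276 genes higher and 3451 lower, 6727 together, with 5624 at least 2-fold apart. With only these lines in the fit the count was 3849.

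Between A28 and YH25005 calls were spread over both subgenomes, with 3253 A genes higher and 2677 lower in A28 and 2644 C genes higher and 2614 lower. BnaC04g34260D was at 105 ± 48.4 CPM and BnaCnng71630D at 98.5 ± 29.1 CPM in A28. Before TMM scaling they were at least 4010-fold and 3760-fold above YH25005. BnaA03g35720D was at 187 ± 55.5 CPM in YH25005 and at least 5060-fold lower in A28. In all 6328 genes were higher and 5564 lower in A28, 11892 together, and 9565 differed at least 2-fold. The excess of higher genes did not hold without YH25005 replicate 1 (3722 higher, 3733 lower), with the replicate block (6345 and 6491) or with a within-line covariate (8800 and 9076). The count fell to 7884 with only these lines in the fit, to 7455 without YH25005 replicate 1 and to 7550 without YH25005 replicate 3. It was the highest of the 6 pairs with all libraries in the fit, but R8Q10 and SW led in both of these omissions (9578 and 9483), and SW and YH25005 led without A28 replicate 1 (11374 against 9569), without A28 replicate 3 (13733 against 9425) and with only the compared lines in the fit (14333).

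R8Q10 and SW differed on A10, with 86 of 1489 genes higher and 794 lower in R8Q10, and on C9, with 487 of 2151 higher and 159 lower. On A3, 455 of 2825 genes were lower in R8Q10, and on C3, 482 of 3214 were higher. BnaA10g19670D was at 471 ± 169 CPM and BnaA02g30780D at 321 ± 51.9 CPM in SW, at least 17100-fold and 11700-fold above R8Q10. BnaA09g21960D was at 131 ± 99.3 CPM in R8Q10 and, before TMM scaling, at least 4690-fold lower in SW. The test called 4914 genes higher and 5407 lower, 10321 together, with 8442 at least 2-fold apart.

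R8Q10 and YH25005 also differed on A10 and C9, with 116 of 1489 A10 genes higher and 756 lower in R8Q10 and 532 of 2151 C9 genes higher and 170 lower. BnaA02g30780D was at 378 ± 121 CPM and BnaA10g23630D, inside the low A10 run, at 344 ± 108 CPM in YH25005, at least 10800-fold and 9820-fold above R8Q10. BnaC01g37760D, in a run that was low in YH25005, was at 59.3 ± 3.5 CPM in R8Q10. Before TMM scaling it was at least 2250-fold lower in YH25005. In all 4663 genes were higher and 5554 lower in R8Q10, 10217 together, and 8179 differed at least 2-fold. Single libraries mattered: the count was 6191 without YH25005 replicate 1, 6288 without YH25005 replicate 3, 6638 without R8Q10 replicate 1 and 6404 without R8Q10 replicate 3.

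SW and YH25005 differed on A3, with 544 of 2825 genes higher and 265 lower in SW, and on C3, with 293 of 3214 higher and 532 lower. BnaCnng71630D was at 101 ± 13.8 CPM and BnaA06g03330D at 68.2 ± 8.45 CPM in SW. Before TMM scaling they were at least 3630-fold and 2450-fold above YH25005. BnaCnng02680D was at 117 ± 6.8 CPM and BnaC03g07200D at 103 ± 18.8 CPM in YH25005, at least 3220-fold and 2790-fold above SW. The test called 5933 genes higher and 5726 lower, 11659 together, with 9368 at least 2-fold apart. Lower genes were the more frequent without YH25005 replicate 1 (3904 higher, 3958 lower), without YH25005 replicate 2 (5011 and 5039) and with the within-line covariate (8301 and 8690).

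**Figure D4:**
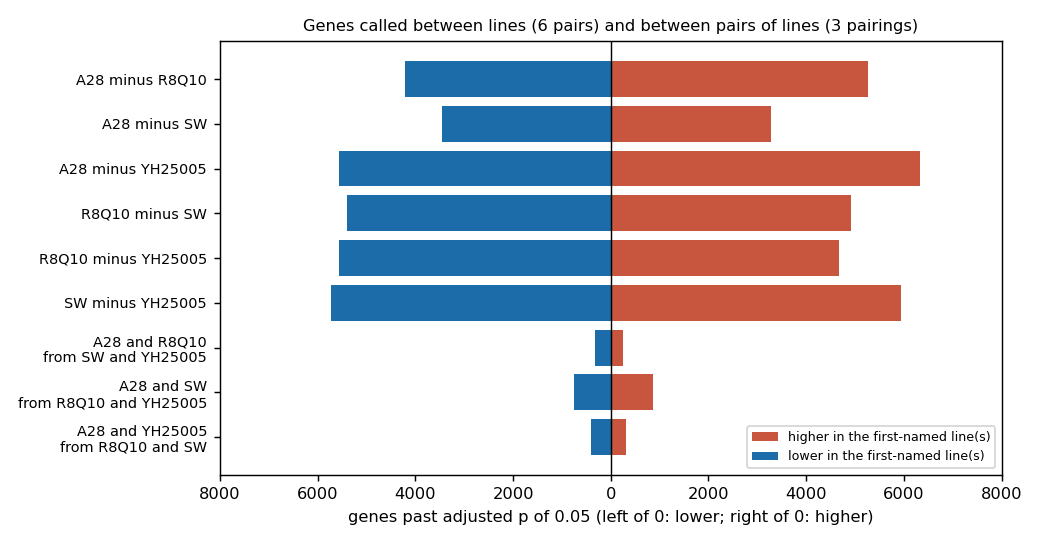
Number of genes called at an adjusted p of 0.05 in the 6 line pairs and the 3 pairings, with genes higher in the first-named line or lines to the right of 0 and lower ones to the left. The pairs range from 6727 genes (A28 and SW) to 11892 (A28 and YH25005), and the pairings from 565 to 1607.

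The labels do not say how many lines are high or low in linolenic acid. Divisions of the lines into pairs, of which there are 3, were compared, and divisions of 1 line against the rest were not analysed here. Genes that separated A28 and SW from R8Q10 and YH25005 were the most frequent, with 858 higher and 749 lower in A28 and SW, 1607 together, 1330 of them by at least 2-fold in all 4 contrasts. BnaAnng29540D was at 72.6 ± 38.1 CPM in A28 and 24.3 ± 2.19 CPM in SW, with 0 counts in R8Q10 and YH25005. BnaC04g08330D was at 25.1 ± 4.78 CPM in R8Q10 and 26.1 ± 5.24 CPM in YH25005, with 0 counts in A28 and SW. BnaC06g40300D, inside a C6 run low in A28 and SW, showed 23.6 ± 3.41 and 25 ± 3.48 CPM against 0 counts.

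Genes that separated A28 and YH25005 from R8Q10 and SW numbered 715, with 317 higher and 398 lower in A28 and YH25005. On C9, 76 of 2151 genes were lower and 9 higher. BnaC03g07200D was at 132 ± 58.2 CPM in A28 and 103 ± 18.8 CPM in YH25005, with 0 counts in R8Q10 and SW. BnaA06g03330D was at 30.3 ± 2.3 CPM in R8Q10 and 68.2 ± 8.45 CPM in SW, with 0 counts in the other two.

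Genes that separated A28 and R8Q10 from SW and YH25005 numbered 565, with 248 higher and 317 lower in A28 and R8Q10, of which 211 of the lower genes lay in the A subgenome. BnaC01g37840D, in a C1 stretch low in SW and YH25005, was at 31.6 ± 3.41 CPM in A28 and 31.3 ± 7.24 CPM in R8Q10, against 1.4 ± 0.233 CPM in SW and 0 counts in YH25005. BnaA09g47050D was at 17.7 ± 3.21 CPM in SW and 17.3 ± 3.54 CPM in YH25005, against 1.03 ± 0.42 CPM in A28 and 1.12 ± 0.372 CPM in R8Q10. This count moved with single libraries, to 972 without A28 replicate 2 (496 higher and 476 lower, so the excess of lower genes did not hold), 345 without SW replicate 2, 359 without YH25005 replicate 1 and 352 without YH25005 replicate 3. DESeq2 called 921. The libraries of each of these pairs also share a gene list of their own, and genes filtered from either list could not enter this count.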

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

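The tests of mixing and of development in this part were chosen after the values had been seen. The gene BnaA01g16230D reached 9920 ± 3110 CPM (SD, n = 3) in YH25005 and had 0 counts in all 3 SW libraries. It is listed only for SW and YH25005, so it entered none of the comparisons made on genes of both lists, and it was noted because its level lies far above the limit that a count of 0 allows. BnaA08g31350D, listed for the same libraries, reached 1120 ± 327 CPM in YH25005 and 34.3 ± 29.6 CPM in SW.

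In the median of 46 genes of at least 1000 CPM in YH25005, both of these among them, SW replicate 2 reached 9.19% of the YH25005 level and SW replicate 3 reached 3.33%. Mixing of YH25005 material into SW replicate 2 would add the same percent to every gene, but at the median gain of 4.63% it predicts 15300 counts of BnaA01g16230D, where 0 were found, and 5 of the 46 genes stayed more than 10 times below that percent and 14 below it, which argues against mixing there. A difference in developmental progress between seeds stays open, as all samples carry the same age and no stage marker could be named. Of the 50 most abundant YH25005 genes among those in both lists, 44 were higher in SW replicate 2 than in SW replicate 3. In R8Q10 43 were higher in replicate 1 than in 3, and in A28 32 were (median log2 differences 1.84, 1.04 and 0.56). These libraries were picked by the level of this set, so the counts decide nothing. Mixing was tested for SW only. Leaving the 50 most abundant genes out of the scaling gave 11665 calls for SW minus YH25005 against 11659, a setting that hardly moved the scaling and decides nothing about their share of the counts.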

How the results depend on the processing

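The alternatives with a within-line covariate, without genes inside runs, with all genes of a shared list, with a block in a fit of A28 and R8Q10 alone and with other run settings were chosen after seeing the data. All named IDs kept their direction and passed the threshold in each of the 719 combinations of ID and setting that gave a value. The fits of only the lines compared were not among these settings, and the filter settings repeat the main fit. The IDs had been picked for large folds without overlap, which favours this outcome. With only the lines compared, A28 minus R8Q10 gave 6209 calls, A28 minus SW 3849 and A28 minus YH25005 7884, all fewer. R8Q10 minus SW gave 10575, R8Q10 minus YH25005 13699 and SW minus YH25005 14333, all more. The pairs that fell contain A28, whose biological coefficient of variation was 0.5, against 0.34 in R8Q10, 0.35 in SW and 0.26 in YH25005. The fit of all libraries shares 1 estimate of the spread per gene over the lines. Counts for A28 there thus rest partly on the smaller spread of the other lines. Whether this accounts for the changes was not tested. With all genes of the shared list and only the lines compared, A28 minus R8Q10 gave 7459 and SW minus YH25005 16233. DESeq2 gave 921 genes separating A28 and R8Q10 from SW and YH25005 (the cause was not tested). With the covariate, calls rose to 11349 for A28 minus SW, 17876 for A28 minus YH25005, 16453 for R8Q10 minus YH25005, and 1791, 2655 and 1092 for the pairings of A28 with R8Q10, SW and YH25005. The covariate was taken from these same counts, as the component with 39.2% of the variance within lines. A fit with it has less residual spread by construction, so the rise in calls decides nothing.

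Without single libraries the counts ranged from 15718 to 24086 over the 4 lines, 7125 to 10871 for A28 minus R8Q10, 4871 to 9599 for A28 minus SW, 7455 to 15888 for A28 minus YH25005, 7640 to 11871 for R8Q10 minus SW, 6191 to 12503 for R8Q10 minus YH25005 and 7862 to 13733 for SW minus YH25005. For the pairings of A28 with R8Q10, SW and YH25005 they ranged from 345 to 972, 1245 to 1863 and 561 to 796.

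Beyond A28 and R8Q10, the replicate numbers were not taken to pair the samples: over all line pairs same-numbered libraries had correlations of deviations from -0.3 to 0.58, and 6 of 12 libraries correlated best with their own number. On the main component within lines, the replicates ran in the same order in A28, R8Q10 and SW. By replicate number the scores were 0.081, -0.63 and 0.55 in A28, and 0.011, -0.31 and 0.3 in R8Q10. They were 8e-05, -0.19 and 0.19 in SW, but -0.14, 0.11 and 0.034 in YH25005. A factor that SW shares with A28 and R8Q10 by replicate number is therefore not excluded. For A28 and R8Q10 alone the block gave 9133 calls. With the replicate block the counts were 20827 over the 4 lines, 9524, 6791, 12836, 10586, 11096 and 12220 for the pairs in the order above, and 588, 1660 and 735 for the pairings. The filter settings removed 0 genes and say nothing about stability. The alternatives for FPKM values did not apply, and those for gene lists were not run because the lists had 0 matched members. Outside the runs, the pairings kept 459, 1406 and 556 genes. The number of low runs was 26 to 28 and of raised runs 17 to 20 under other settings. At this depth a gene with 0 counts in a library may still be present below 0.0995 CPM.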

Other observations

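The tests on runs, and the comparison of splits that part same-numbered libraries, were chosen after results had been seen, and those on other splits of the libraries and on neighbouring genes before their results were seen. Low runs differed in number and extent between lines. SW had 9 with 497 scored genes, A28 7 with 366, R8Q10 7 with 729 and YH25005 3 with 176. Some stretches were low in more than 1 line: the C6 run from BnaC06g40270D in A28 overlapped the one from BnaC06g40240D in SW, and A28 and SW shared a low stretch of C1. Not every low run had a raised counterpart. In A28 a run of 26 A1 genes lay at -6.35, and 14 of its genes had at most 3 counts over the 3 libraries.

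Replacement of a chromosome segment by its homoeologous copy may account for the low runs. Of 26 low runs, 17 had a raised run of the same line on the homoeologous chromosome, more than under any other of the 24 ways to assign the line names, but by a small margin (highest other 16, median 10.5, exact permutation p = 0.042, the smallest 24 namings can give). Deletion with no change elsewhere was first tested on the whole of C9 in R8Q10. Its median of 0.2 lay close to the 0.15 of the next C chromosome and decided nothing. The low runs of 20 or more genes were then taken. Of these 15, 13 had a raised run as above, against at most 11 under other namings (exact permutation p = 0.042, again the smallest possible). The margin is small, and the 20-gene limit and the list of homoeologous chromosomes were set after the runs were seen. This goes against deletion alone only weakly. It says nothing against deletion for the runs without a raised counterpart, 26 A1 genes in A28 and 26 C6 genes in SW. Reads of a diverged segment aligning to the other copy would also lower one run and raise the other, and replacement and misalignment cannot be told apart without the reads: summed CPM over paired runs was 0.938 of the median of the other lines for A10 and C9 in R8Q10 (1415 genes), 1.2 for C3 and A3 in SW (508 genes) and 0.809 for C8 and A9 in A28 (171 genes), sums that depend on where the runs end and decide nothing. The partner test counts chromosomes and not positions.

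The lead of the pairing of A28 and SW against R8Q10 and YH25005 could come from chromosome segments that the paired lines share. Same-sign neighbours among its separating genes were 4.2 times as frequent as in shuffled order (95 against a mean of 22.6, highest of 1000 shuffles 42), but the factor was 11.7 and 21.8 in the other pairings, so clustering was not strongest in this pairing. The factor falls as separating genes become denser, and by the excess over the shuffled mean, 72.4 neighbour pairs in this pairing against 37.5 and 78.2, it did not lead either. Genes inside runs did not account for the lead, since 1406 genes remained outside them against 556 in the next pairing. The count of 565 for A28 and R8Q10 against SW and YH25005 could not include genes filtered from either gene list. The lead over that pairing may come partly from this filter, which was not tested. Which lines share the oil trait was not tested, as the labels do not give it.

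Other splits of the libraries show what counts arise when the libraries are grouped at random. Over the 4 lines 1 of 100 splits, the real one, gave as many as 20209 genes, and the highest other gave 4559. Splits that mix lines widen the spread within their groups, which lowers their counts. The splits therefore show that libraries of a line resemble each other more than random groups do. They cannot exclude differences between plants, plots or batches that coincide with the lines. For the pairings, 1 of 100 splits gave as many as 565, 1607 or 715 genes, with 190 as the highest count of any pairing in the other splits. For the 6 pairs, 10 splits are too few for a share under 0.05. There 1 of 10 gave the real count, and the highest other split gave 1 gene for A28 minus R8Q10 (9463), A28 minus SW (6727), A28 minus YH25005 (11892) and R8Q10 minus YH25005 (10217), and 2 genes for R8Q10 minus SW (10321) and SW minus YH25005 (11659). For A28 and R8Q10, 4 of the splits part all 3 same-numbered pairs, and of these only the real one reached its count, which is too few splits for a share under 0.05.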
